A study of Homo sapiens with 8 samples.

How the data were processed

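Ribosomal RNA-depleted total RNA was sequenced from K-562 cells, an established human leukaemia cell line. Per the labels' protocols, knockout clones were made with CRISPR/Cas9 plasmids and grown from single sorted cells, and cells then received a lentivirus with an empty vector or a FLAG-tagged transgene. The libraries were made with NEBNext kits and amplified for 13 PCR cycles, without molecular identifiers being named. The 8 libraries analysed here form 4 groups of 2. These are wild-type controls with a negative guide RNA, TASOR knockout cells, TASOR knockout cells expressing FLAG-TASOR, and wild-type cells expressing FLAG-TASOR2. The series design calls the 2 libraries of a group biological replicates. Whether they came from separate clones is not given in the sources used here, so the p-values measure the spread between these libraries.

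The submitters' processing notes name STAR 2.7.8, Salmon, edgeR, DESeq2 and the hg38 genome build, without a role for each. The values used here come from 3 gene tables, each a comparison of one group with the wild-type controls. Per the file headers, each deposited table gives a log2 fold change, a log2 mean expression (logCPM), an F score, a p-value and an adjusted p-value for each gene. The column names that the authors used are those of an edgeR quasi-likelihood F-test table, but the notes do not state which tool made the tables. The deposited log2 fold changes are positive where a gene was higher in the altered cells than in the controls. The F score was used as the authors deposited it, and the deposited p-value and adjusted p-value were not recomputed. Tables of transposable elements are named in the labels and were not used here. Results for some genes are not reported here.

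The tables list only part of the genes. Every listed gene had an unadjusted p below 0.05, an absolute log2 fold change above 1 and a log2 mean expression above 1, as checked on the values. No threshold on the adjusted p was applied in the tables. A gene is therefore said to have risen or fallen only where its deposited adjusted p was below 0.05, and other genes are called listed as higher or lower. A gene missing from a table is not shown to be at the control level. The tables hold no value per library, so no model was refitted, and the depth of each library is unknown from them. No interval or detection limit that needs a depth is given.

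Several quantities were recovered from the tables. The number of genes tested was taken from the ratio of adjusted to unadjusted p of the top gene, which worked for 2 of the tables. An approximate standard error was computed as the absolute log2 fold change divided by the square root of F. The total degrees of freedom of the F-test came to 5.36 for the knockout, 5.34 for the FLAG-TASOR and 6.01 for the FLAG-TASOR2 table, which points to a separate fit for each. A gene whose degrees of freedom were lower by 1 was taken to have all counts of a group at 0, which is how the authors' quasi-likelihood test would treat such genes if edgeR made the deposited tables. This held for 9, 8 and 14 listed genes, for which no fold is given. Gene positions, exon numbers and classes came from GENCODE 29 on GRCh38, the same assembly as hg38, matched by Ensembl identifier. Of the listed genes, 257 of 268, 253 of 261 and 853 of 884 were matched.

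Before the data were examined, 21 gene lists, the tests and the rule for named genes were fixed. The rule took, per table, the 10 highest and 10 lowest log2 fold changes among genes with a symbol and a mean expression at or above the median of the table. It also took TASOR, TASOR2 and listed genes of the HUSH list, up to 4 members of each list by adjusted p, and up to 10 genes listed in all 3 tables. The zinc finger list was defined by symbol. For lists with at least 5 listed members, the numbers listed as higher and lower were compared with those of all other genes of the same table by a two-sided Fisher's exact test. Benjamini-Hochberg adjustment covered the 10 such tests. Gene span and exon number were compared by two-sided permutation tests with 100000 resamples, and shares on chromosome 19 by Fisher's exact test, with adjustment over the family. Clustering was tested by permuting signs among listed genes 100000 times (one-sided), counting neighbouring genes within 1 Mb that had the same sign. A run was defined as at least 8 listed genes of one sign with gaps of at most 2 Mb. The search for runs and the tests per chromosome were chosen after the data had been seen.

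The 3 comparisons share the same control libraries. The overlap between tables was therefore set beside 100 simulations of unchanged groups against shared controls, with the spread chosen so that chance alone lists as many genes as the knockout table. Each simulated list was cut to the length of its deposited table. At 884 genes, the simulated FLAG-TASOR2 lists therefore held genes short of the listing thresholds, which can raise their overlaps. The controls could not be split, since only 2 libraries were used. The list, permutation and clustering tests were tested on simulated data. Without an effect they gave p below 0.05 in 2 to 7% of draws. The simulated list members were drawn at random and signs were permuted freely. These rates therefore do not cover lists whose members lie side by side. Planted list effects (11 of 12 members made higher) and median effects (a shift of 0.8 SD) were found in 100% of draws. Smaller lists and weaker effects were not planted. Planted clustering (sign copied from the neighbour for 40% of genes) was found in 93% (knockout, 257 genes), 54% (FLAG-TASOR, 253 genes) and 100% (FLAG-TASOR2, 853 genes). Alternatives tried were stricter adjusted p, larger folds, higher expression, protein-coding genes only, nearer neighbours, and lists or chromosomes left out. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.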

Results

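Total RNA was compared between K-562 cells with altered dosage of 2 related proteins and wild-type control cells. TASOR is a subunit of the human silencing hub (HUSH), a complex that represses LINE-1 retrotransposons and some genes, and TASOR2 is its paralog. The 8 libraries form 4 groups of 2, and each of the 3 altered groups was compared with the same controls. The authors' deposited tables listed 268 genes for the TASOR knockout, 261 for the knockout expressing FLAG-TASOR and 884 for wild-type cells expressing FLAG-TASOR2. Depth per library is unknown from these tables. All fold changes below are the authors', and values in parentheses after those of single genes are approximate SEs derived from their F score.

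The first comparison asked which genes changed when TASOR was lost. TASOR itself (chromosome 3, 56620133 to 56683237) was listed as lower in the authors' deposited table, with a log2 fold change of -1.08 (approximate SE 0.23, p 0.00481, adjusted p 1.00). TFPI, which encodes an inhibitor of the tissue factor pathway of coagulation, rose by a log2 fold change of 4.86 in the authors' deposited table (approximate SE 0.19, adjusted p 0.0114). It lies on chromosome 2 at 187464230 to 187565760. TFPI was the only gene of this table with an adjusted p below 0.05. In all, 137 genes were listed as higher and 131 as lower.

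The clearest group was the gamma protocadherins, cell-surface adhesion proteins encoded in a cluster on chromosome 5. All 17 listed members were higher, between 141330571 and 141512981, with a median log2 fold change of 3.94 in the authors' deposited table. Against the rest of the table, this gave an adjusted p of 3.19e-05 (Fisher's exact test). Of these, 15 passed 0.05 when adjusted over the list alone and 0 over all genes. In the authors' deposited table PCDHGA4 had a log2 fold change of 4.91 (approximate SE 0.56, adjusted p 0.628) and PCDHGA8 one of 3.94 (approximate SE 0.59, adjusted p 0.839). The gamma genes share constant exons, so their counts are not independent, and the 17 genes form 1 locus. Only 2 of the 17 reached the median expression of the listed genes.

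Zinc finger genes were also listed mainly as higher, 18 against 3 lower (adjusted p 0.00205, Fisher's exact test). None passed 0.05 when adjusted over the list alone (0 genes). In the authors' deposited table ZNF776 had a log2 fold change of 1.85 (approximate SE 0.27), ZNF772 one of 2.19 (0.38) and ZNF418 one of 3.02 (0.69). At the distal end of chromosome 19, between 57466663 and 57935393, 14 of 14 listed zinc finger genes were higher, with a median of 1.84 in the authors' deposited table. That interval was chosen after its values were seen. With members within 1 Mb counted as 1 locus, the adjusted p rose to 0.727 (4 loci higher, 2 lower). Chromosome 19 as a whole held 26 higher and 3 lower genes (adjusted p 2.08e-05, Fisher's exact test), and 18 and 3 with protein-coding genes only (adjusted p 0.000445). Of the 26, 15 lie in 1 run within that distal interval. The chromosome test counts neighbours as independent and was not run by locus.

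The highest log2 fold change among the named genes of this table was that of a germline gene. TDRD6, a Tudor-domain gene of germ cells, was listed with a log2 fold change of 8.63 (approximate SE 1.19, adjusted p 0.839) in the authors' deposited table, and TDRD5 with 4.87 (0.70). XAGE1B, also in the cancer-testis list, was listed as lower at -1.92 (0.52) in the authors' deposited table, so the 3 listed members did not share a direction and were too few to test. TSPYL6 was listed at 3.45 (0.36) in the authors' deposited table. Among lower genes, LIFR, a cytokine receptor subunit, had a log2 fold change of -2.97 (0.33), MBNL3 one of -3.29 (0.52) and CREB5 one of -3.30 (0.96) in the authors' deposited table. The 3 listed interferon-stimulated genes, TAP1, GBP2 and OAS3, were lower and too few to test. Genes listed as higher had fewer exons than those listed as lower, with medians of 6 and 9 (adjusted p 0.0242, permutation test), while gene span did not differ detectably (adjusted p 0.821). With zinc finger genes left out, the adjusted p for exon number was 0.0655. The test counts genes as independent, and it was not run without the 17 protocadherins, which form 1 locus.

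The authors' test covered 13992 genes, of which 699.6 are expected at p below 0.05 by chance, and at most 697 had a p up to the largest listed. The single genes other than TFPI are therefore not distinguished from chance one by one. The list tests ask only about direction among listed genes.

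**Figure D1:**
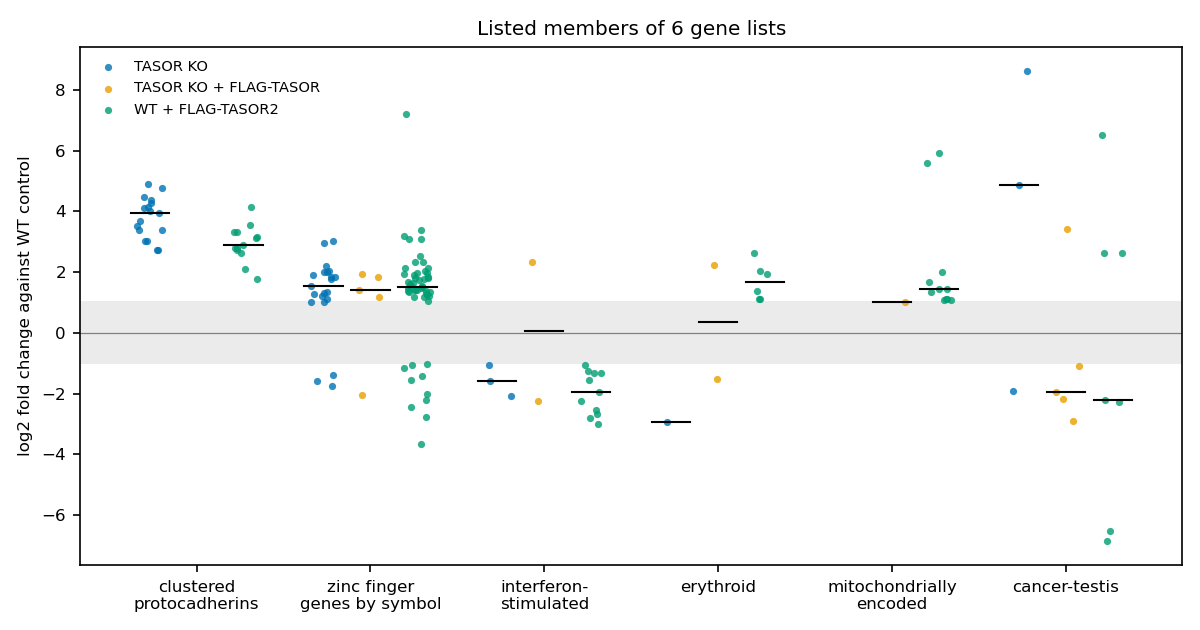
Log2 fold change against wild-type controls (y axis) of the listed members of 6 gene lists (x axis), for the 3 comparisons in colour. Each point is a gene from the authors' deposited tables, black bars are medians and the grey band is the range that the tables leave out. All 17 and 13 listed protocadherins lie above 0 in the knockout and FLAG-TASOR2 tables, and none is listed with FLAG-TASOR.

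The second comparison asked how knockout cells expressing FLAG-TASOR differed from the same controls. No gene of this table passed an adjusted p of 0.05 (0 of 261, all listed at an unadjusted p below 0.05 of the deposited edgeR-type F-test), and the smallest adjusted p was 0.999 in the authors' deposited table. Neither TASOR nor TASOR2 was listed. More genes were listed as lower (176) than as higher (85). No gamma protocadherin was listed, against 17 in the knockout table. The difference between the 2 groups was not tested, since unlisted genes have no value here.

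TFPI was listed with a log2 fold change of 1.70 (approximate SE 0.32) in the authors' deposited table for FLAG-TASOR, against 4.86 (0.19) without it. TDRD5 was at 3.41 (0.82) in the authors' deposited table for FLAG-TASOR. HBE1, an embryonic globin gene, was listed as higher at 2.24 (0.57), and UTRN at 2.33 (0.68), in the authors' deposited table. CA2, like HBE1 in the erythroid list, was lower at -1.53 (0.46), and at -2.95 (0.55) in the knockout, in the authors' deposited tables. The lowest included NXF2 at -6.76 (1.83), COL14A1 at -4.78 (1.54) and NEO1 at -4.59 (0.94) in the authors' deposited table. Zinc finger genes were listed as 4 higher and 1 lower (adjusted p 0.0501, Fisher's exact test), and cancer-testis genes as 1 higher and 4 lower (adjusted p 1). Interferon-stimulated genes were split, with EPSTI1 higher at 2.35 (0.83) and APOL1 lower at -2.25 (0.54) in the authors' deposited table. Exon number did not differ detectably, with medians of 8 for higher and 10 for lower genes (adjusted p 0.314, permutation test), nor did gene span (adjusted p 0.248). Chromosome 19 held 10 of 83 higher and 6 of 170 lower genes that matched the annotation (adjusted p 0.0242, Fisher's exact test). This call was lost with protein-coding genes only (adjusted p 0.197), and in the family of all chromosomes its adjusted p was 0.0893. On chromosome X, 29 listed genes were lower and 1 higher (adjusted p 0.00127, Fisher's exact test). On X, 67 were lower and 13 higher with FLAG-TASOR2 (adjusted p 0.000107), and 15 lower and 6 higher in the knockout (adjusted p 0.157). All 3 comparisons use the same controls, so a shared direction on X is no independent evidence. Chromosome 1 leaned the other way with FLAG-TASOR, 15 higher and 7 lower (adjusted p 0.00527). In the knockout, chromosome 19 had an adjusted p of 0.000107 in this family, chromosome 7 had 4 higher and 17 lower (adjusted p 0.0211) and chromosome 5, with the protocadherins, 20 higher and 5 lower (adjusted p 0.0211). The tests in the family of all chromosomes were chosen after seeing the data. All tests per chromosome count neighbouring genes as independent.

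The knockout and FLAG-TASOR tables shared 60 genes, 59 of them with the same sign. Simulated unchanged groups against shared controls shared 61.5 genes on average (42 to 76), with 97.2% of the same sign. Independent lists would share 0.835 higher and 1.65 lower genes. Of the genes listed in the knockout, 18.2% of the higher and 26.7% of the lower ones were listed again (p 0.108, Fisher's exact test). Over 57 shared genes of the same sign, the size of the change differed by a median log2 of -0.29 for higher and 0.03 for lower genes, a difference of -0.33 (p 0.0972, permutation test). The 112 higher and 96 lower genes not listed again have no value and could not enter. The common controls could not be split, so part of this sharing may come from them.

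**Figure D2:**
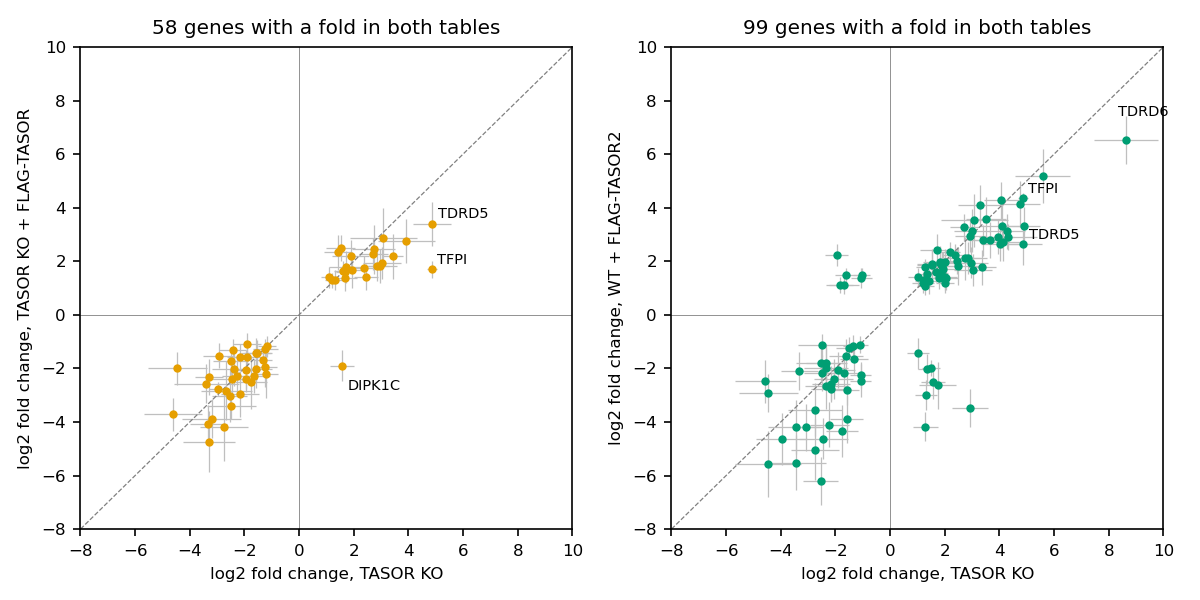
Log2 fold change in the TASOR knockout (x axis) against that in the other 2 comparisons (y axis), for genes with a fold in both of the authors' deposited tables. Bars are approximate SEs and the dashed line marks equal values. TFPI lies below the line with FLAG-TASOR (4.86 and 1.70) and near it with FLAG-TASOR2 (4.86 and 4.36).

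The third comparison asked how wild-type cells expressing FLAG-TASOR2 differed from the same controls. The labels name a negative guide RNA for the controls and no guide for the FLAG-TASOR2 cells. A difference in guide treatment can therefore not be told apart from the transgene. TASOR2 (chromosome 10, 5684838 to 5763740) was listed as higher at 2.26 (approximate SE 0.27, adjusted p 0.125) in the authors' deposited table. Here 5 genes had an adjusted p below 0.05. TFPI rose by 4.36 (0.19, adjusted p 0.00684) and THBS1, which encodes the matrix glycoprotein thrombospondin-1, rose by 3.21 (0.24, adjusted p 0.0353) in the authors' deposited table. The rise of TFPI in the knockout was against the same controls, so the repeat is no independent evidence. PAGE1, a cancer-testis gene, fell by 6.87 (0.48), and TRANK1 fell by 3.71 (0.28) on the log2 scale in the authors' deposited table, both with an adjusted p of 0.0353. EIF3CL also fell, with all counts of a group at 0 and therefore no fold, and it has a near-identical copy that shares its reads. TRANK1 was outside the rule for named genes and was chosen after its values were seen.

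Gamma protocadherins were again listed only as higher, 13 against 0 (adjusted p 3.19e-05, Fisher's exact test), with a median log2 fold change of 2.90 in the authors' deposited table. All 13 were among the 17 of the knockout, and 11 passed 0.05 when adjusted over the list alone. Both comparisons use the same controls, so a repeat of protocadherins or zinc finger genes is no independent evidence. Zinc finger genes were listed as 41 higher and 10 lower (adjusted p 3.31e-08, Fisher's exact test), with 0 past 0.05 adjusted over the list alone. ZNF534 had a log2 fold change of 7.21 (0.82), ZNF772 one of 2.34 (0.36) and ZNF134 one of 1.78 (0.30) in the authors' deposited table. The symbol-based list also holds ZFP36, which encodes an RNA-binding protein. Between 57466663 and 58155110 of chromosome 19, 16 of 16 listed zinc finger genes were higher. By locus the adjusted p was 0.0804 (12 loci higher, 7 lower). Chromosome 19 as a whole held 49 higher and 26 lower genes (adjusted p 2.08e-05, Fisher's exact test), and 38 and 26 with protein-coding genes only (adjusted p 3.35e-05). The 49 include runs of 21, 10 and 9 higher genes, and the chromosome test was not run by locus.

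Interferon-stimulated genes were listed only as lower, 11 against 0 higher (adjusted p 0.00615, Fisher's exact test), and 7 passed 0.05 when adjusted over the list alone. They included TAP1, a peptide transporter of antigen presentation, at -2.81 (0.56), PARP12 at -1.94 (0.26) and BST2, which tethers virus particles, at -1.26 (0.21) in the authors' deposited table. The adjusted p was 0.0652 by locus and 0.0818 among genes of higher expression. Erythroid genes were listed as 6 higher and 0 lower (adjusted p 0.00615, Fisher's exact test), and 4 of them passed 0.05 when adjusted over the list alone. The 6 genes form 4 loci, too few to test by locus. SLC4A1, the red cell anion exchanger, was at 2.62 (0.31) and the alpha-globin gene HBA2 at 2.04 (0.30) in the authors' deposited table. The megakaryocyte genes TUBB1 and GP1BB were listed as higher beside THBS1, at 1.77 (0.25) and 1.59 (0.26) in the authors' deposited table.

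Genes of the mitochondrial genome were listed as 11 higher and 0 lower (adjusted p 0.00011, Fisher's exact test), 9 of them adjusted over the list alone. They form 1 locus, so their number is not a number of independent genes. The ribosomal RNA MT-RNR1 was at 5.90 (2.18) and MT-RNR2 at 5.60 (1.98), while MT-CO2 was at 1.46 (0.24) in the authors' deposited table. These RNAs were listed as higher in the same comparison as the erythroid and zinc finger genes, and joint change was not tested. Cancer-testis genes were split, 3 higher and 4 lower (adjusted p 1), with TDRD6 at 6.51 (0.90) and PAGE2B at -6.51 (0.69) in the authors' deposited table. XIST, the noncoding RNA of X inactivation, was listed at -4.62 (0.59) in the authors' deposited table, and its antisense gene TSIX had a group at 0 counts. Whether counting used strand is not given in the sources used here.

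Genes listed as higher had a median of 5 exons against 10 for lower ones (adjusted p 3e-05, permutation test, from the smallest p of 1e-05 that the resamples can give). With protein-coding genes only, the difference was -3 in place of -5 (adjusted p 0.00678). The test counts genes as independent, but the higher genes include 13 protocadherins and 11 mitochondrial genes, each set in 1 locus. It was not run without them. Gene span did not differ detectably (adjusted p 0.508). Of 14001 genes tested, at most 1710 had a p up to the largest listed, against 700.05 expected by chance at p below 0.05.

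This table shared 100 genes with the knockout, 86 of them with the same sign, where unchanged groups simulated against the common controls shared 92.2 (61 to 108) with 95.1% of the same sign. With the FLAG-TASOR table it shared 60, 54 of the same sign, where the simulations shared 91.4 (73 to 106). The observed number lies below all 100 simulations, so the simulated values overstate the sharing for that pair and are no reliable benchmark for the others. A set of 28 genes was listed in all 3 tables, 14 higher and 12 lower throughout. The same simulations, with no effect, listed 33.1 in all 3 (16 to 48), 31.9 of them with the same sign throughout. These counts also rest on the simulated FLAG-TASOR2 lists, so they cannot decide whether sharing of this size comes from the controls alone. ZNF702P, a zinc finger pseudogene, was one of them, at 1.67 (0.32), 1.59 (0.34) and 1.59 (0.38) in the authors' deposited tables.

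Listed genes of the same sign lay side by side in each comparison. Within 1 Mb, 56 of 63 neighbouring pairs shared a sign in the knockout (31.4 expected, p 1e-05, permutation test), 26 of 32 with FLAG-TASOR (17.8, p 0.00216) and 282 of 369 with FLAG-TASOR2 (191.9, p 1e-05). The value 1e-05 is the smallest these permutations can give. Without zinc finger genes, protocadherins and the mitochondrial genome, chosen after seeing the data, 24 pairs shared a sign in the knockout (15.2 expected, p 0.00092, permutation test). With FLAG-TASOR2, 18 genes adjacent in the list were lower on chromosome 8 between 142727203 and 144507174, where 16 of 71 annotated protein-coding genes were listed. On chromosome X, 20 were lower between 149476990 and 155669944, where 20 of 116 were listed. None of these genes had an adjusted p below 0.05.

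**Figure D3:**
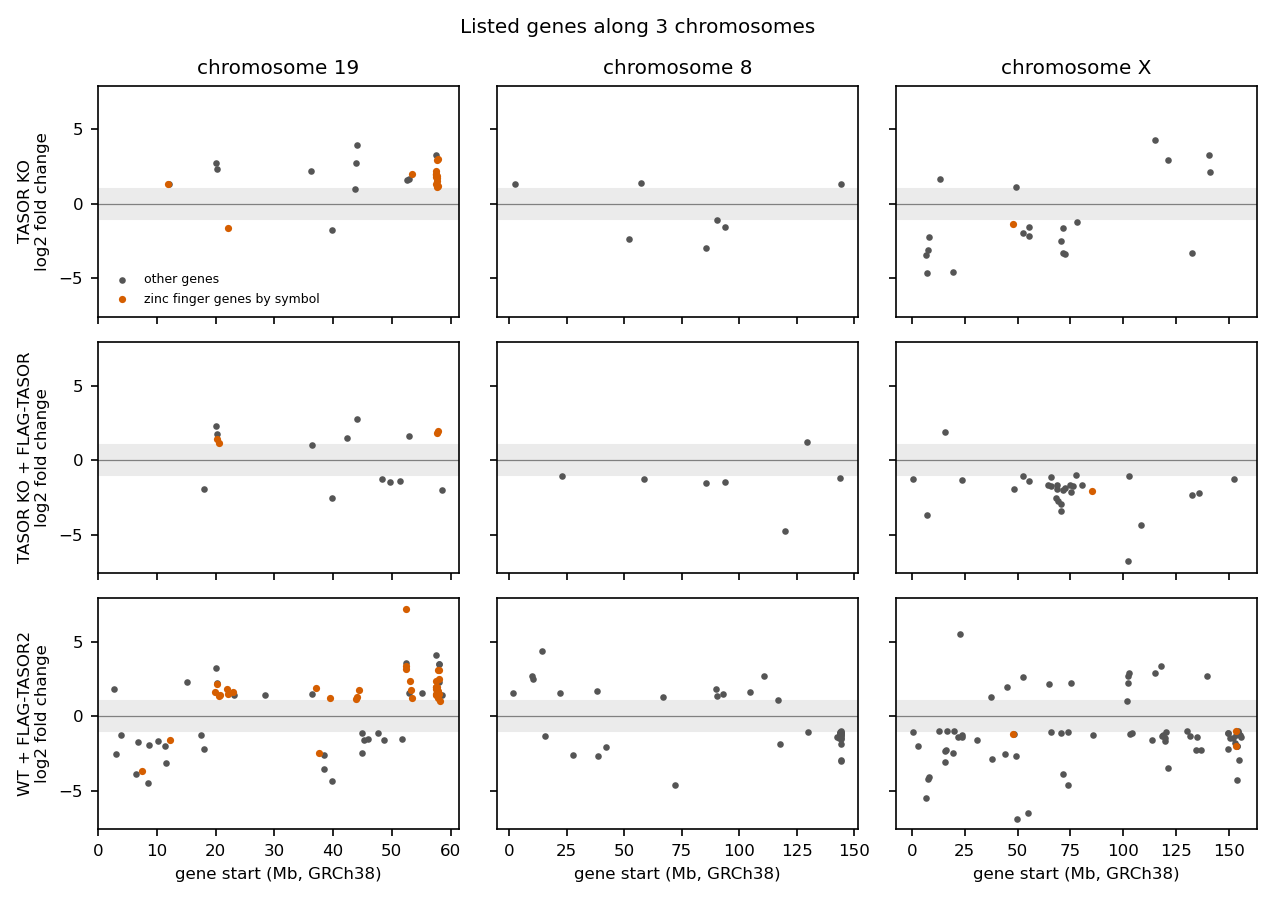
Log2 fold change (y axis) of listed genes by gene start in Mb on GRCh38 (x axis), for chromosomes 19, 8 and X in the 3 comparisons, from the authors' deposited tables. Zinc finger genes are orange, other genes grey, and the grey band is the range the tables leave out. Zinc finger genes near the distal end of chromosome 19 lie above 0, and 18 genes adjacent in the list on chromosome 8 lie below 0 with FLAG-TASOR2.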

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

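All tests of explanations in this part were chosen after the results they bear on had been seen. The criteria for the mitochondrial and gene-sharing tests were also revised after their values had been seen.

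Some genes were listed with opposite signs in 2 comparisons, which was not tested. There was 1 such gene between the knockout and FLAG-TASOR tables (DIPK1C), 14 between the knockout and FLAG-TASOR2 tables, and 6 between the FLAG-TASOR and FLAG-TASOR2 tables. MS4A3 was at -1.96 (approximate SE 0.42), -2.40 (0.48) and 2.24 (0.41) across the 3 comparisons in the authors' deposited tables.

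Listed neighbours that were lower together may reflect a loss of DNA copies in the cells of a group. Growth from single sorted cells is given above for knockout clones only. Of the 4 runs, 3 were in wild-type cells expressing FLAG-TASOR2. A lost segment would lower its genes by one common amount, so the SD of log2 fold within each run was compared with 10000 random sets of lower genes of the same table. The sets were not matched for expression, on which the spread of folds can depend. Log2 folds between -1 and 1 are not listed, so a smaller common loss could not appear. As narrow a spread was found in 24.54% of sets for 8 genes on chromosome X with FLAG-TASOR. With FLAG-TASOR2 it was found in 62.92% for 9 genes on chromosome 19, in 4.32% for 18 genes on chromosome 8 and in 18.33% for 20 genes on chromosome X. The limits for reading these values were revised after the values had been seen, from 5 and 50% to 1.25 and 98.75%, to allow for 4 runs. Under the first limits chromosome 8 would have counted for copy loss and chromosome 19 against it, and under the revised limits none of the 4 is decided. Copy loss and regional silencing cannot be told apart here, because unlisted genes of the segments have no value and no DNA was measured.

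The mitochondrial RNAs with FLAG-TASOR2 may in part reflect less complete removal of ribosomal RNA. The 2 mitochondrial ribosomal RNAs lay above the median of the 9 listed messengers by a log2 of 4.41, where a gap of 5.33 would be needed given their larger approximate SE of 2.18, so this stays open for them. The depletion does not target the messengers, yet 9 of 13 were higher past 0.05 when adjusted over the fixed list alone (0 over all genes). These messengers lie in 1 locus, and the criterion was set after their values were seen. The test therefore does not settle the question for them either. MT-RNR2 was also listed as higher with FLAG-TASOR, at 1.02 (0.25) in the authors' deposited table. The cytosolic 5.8S copies RNA5-8SN2 (higher with FLAG-TASOR2) and RNA5-8SN5 (lower in the knockout) each had a group at 0 counts, and near-identical copies share their reads.

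The genes shared by the knockout and FLAG-TASOR tables could come from chance values of the shared controls. Simulations without any effect shared up to 76 genes, and 60 were observed. The same simulations shared at least 73 genes for the FLAG-TASOR and FLAG-TASOR2 tables, where 60 were observed, so they overstate sharing there and the explanation stays open. A transgene acting on the higher genes only would shrink these more than the lower ones. The difference of median change was -0.33 (p 0.0972, permutation test), but this test decides nothing. Of the 25 higher and 35 lower genes listed again it holds only 23 and 34, those with the same sign and a usable fold in both tables, and 112 of 137 higher genes, all 17 protocadherins among them, were not listed again and have no value.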

How the results depend on the processing

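Of 107 alternatives, 32 remove no gene (a log2 fold of at least 1, where the tables start) and 3 keep a fixed share of a table (its median expression), so neither kind tests anything. Of the other 72, 56 stayed the same by set limits. These were a count within a factor of 1.5, a test on its side of 0.05, or a median change within its SD. A count moved in 9, a call was lost in 6 and gained in 1, and 0 reversed a direction that passed 0.05. At an adjusted p below 0.01 too few genes were left to run the list, overlap, transgene, exon, span or clustering results. Those runs are not among the 72 and were not counted as lost. Directions short of 0.05 were not always kept. With protein-coding genes only, the log10 gene span difference went from 0.022 to -0.017 in the knockout and from -0.045 to 0.095 with FLAG-TASOR2. The FLAG-TASOR exon difference went from -2 to 0. The listed genes (268, 261 and 884 for knockout, FLAG-TASOR and FLAG-TASOR2) became 0, 0 and 1 at an adjusted p below 0.01, 0, 0 and 0 below 0.001, 134, 96 and 382 at a log2 fold of at least 2, and 134, 131 and 442 at or above median expression. At median expression or above, the interferon list had an adjusted p of 0.0818 (5 members). Too few protocadherins were left to test there, 2 of 17 in the knockout and 0 of 13 with FLAG-TASOR2. With members within 1 Mb counted as 1 locus, chosen after seeing the data, adjusted p was 0.727 for zinc finger genes in the knockout, and 0.0804 for zinc finger and 0.0652 for interferon genes with FLAG-TASOR2. Fewer units enter those tests. The protocadherin, mitochondrial and erythroid lists fell to 1, 1 and 4 loci and were not tested. With protein-coding genes only, the FLAG-TASOR excess on chromosome 19 was 5.22 percentage points (adjusted p 0.197) and that of zinc finger genes 5.67 points (adjusted p 0.04999, just past the threshold). Without zinc finger genes, the exon difference in the knockout stayed at -3 (adjusted p 0.0655). The cause of these changes was not tested. No paired analysis was possible because the tables hold no values per library. For the same reason leaving out replicates, DESeq2, other size factors, no filter on low counts and the fit with a replicate block were not run, and what depth limits is unknown.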

Other observations

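Several other gene groups had listed members with FLAG-TASOR2. The 4 listed replication-dependent histone genes were all lower, with H3C4 at -1.28 (approximate SE 0.38) and H3C12 at -1.07 (0.28) in the authors' deposited table. KRT19, a keratin, was at -3.75 (0.60) and FN1, which encodes fibronectin, at -3.41 (0.82) in the authors' deposited table. The myeloid integrin gene ITGAM was listed as lower in all 3 comparisons, at -2.44 (0.91), -2.39 (0.70) and -4.62 (0.78) in the authors' deposited tables. NDN, an imprinted gene of chromosome 15, was listed as higher in all 3, at 3.08 (1.22), 2.87 (1.12) and 3.53 (0.98) in the authors' deposited tables. The 3 comparisons share their controls, so these repeats are no independent evidence.

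With FLAG-TASOR2, 11 genes of the U1 small nuclear RNA family were listed, all 11 higher, with log2 fold changes of 1.20 to 1.47 in the authors' deposited table. These near-identical copies share reads, so their number is not a number of independent genes. Of the 21 lists, 5 had no listed member in any table.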
